A study of Homo sapiens with 10 samples.

How the data were processed

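Total RNA from ESCC cell lines, cultured cells of human origin, had been sequenced with standard Illumina library preparation, per the labels. The 10 libraries fall into 4 groups: untreated and IFN-β-treated cells of KYSE30, KYSE180 and KYSE450 (6 libraries), and vector control and IRF1-AS knockdown cells of KYSE30 and KYSE180 (4 libraries). Per the labels' protocols, IFN-β was given at 1000 IU/ml for 72 h with saline buffer as its control, and knockdown used lentivirus made in HEK293T cells. The submitters' processing notes name TopHat, HTSeq and the hg38 genome build, without versions or the role of each. The annotation, the strand setting and the read depth are not given in the sources used here.

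The deposited values are FPKM, per the file headers, in 1 table per library. Each table of the IFN-β experiment stacks 28032 long non-coding transcripts and 20502 named genes, which are mostly protein-coding. The authors' FPKM in the named-gene part sum to between 988427 and 993533 in each library, as values rescaled to a sum of 1000000 would, and the long non-coding part sums to between 50038 and 92837. The tables of the knockdown experiment hold 23555 genes whose FPKM sum to between 399081 and 425340, of which 2974 are unnamed transcripts. The experiments were therefore normalized separately and were tested separately. FPKM carry no depth, the values gave no whole reads that could be recovered, and the precision of a single library is not known.

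The tests fixed before the data were examined assumed read counts, with a fallback for normalized values. The files hold FPKM, so the fallback was used and count-based tests were not run. The design, the gene lists, the rule for named genes and most alternatives were fixed at the same point. The use of the values as deposited, without rescaling, the filter, and FPKM minimums in place of minimums on counts were settled once the unit was known. Long non-coding RNAs were to be taken by annotated biotype, and were taken instead as the genes of the long non-coding part of the table.

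Long non-coding transcripts were summed per gene (16044 genes), and 946 copies on alternate haplotypes of the knockdown tables were added to their primary gene, which left 22609 genes. A gene was tested if it reached 1 FPKM in at least 3 libraries of the IFN-β experiment or 2 of the knockdown experiment. Values were taken as log2(FPKM + 1), so fold changes understate the change of genes with low values. They were fitted with limma 3.58.1 (trend and robust options, with statmod 1.5.0) in R 4.3.3, with the cell line as a block and the treatment as the effect, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Same-numbered libraries came from the same cell line. In the IFN-β experiment the deviations of the 2 libraries of a line from their group means correlated across genes at 0.908 in KYSE30, 0.839 in KYSE180 and 0.873 in KYSE450. A second fit used median-of-ratios scaling, and log2 fold changes called scaled come from it.

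Gene positions come from GENCODE release 29 (GRCh38). Symbols were matched by identifier or by older names, which found a current name for 19784 of 20502 named genes in the IFN-β tables and for 19336 of 19635 Ensembl genes in the knockdown tables. The antisense gene of IRF1 was taken by identifier and position in the knockdown tables, and by the symbol C5orf56, which the references link to it, in the IFN-β tables. The named genes are IRF1, its antisense gene, STAT2, IRF9 and ISG15, then the 10 largest rises and falls among called genes with an average of 5 FPKM or more, a symbol that is not a clone name, and 1 direction in every line. They further include up to 4 members of each list and the 5 long non-coding RNAs with the smallest p in each direction. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p are given as values. Within a line, genes were counted at a 2-fold change and an average of 1 FPKM over the pair, and the 3 largest ratios in each direction at an average of 5 FPKM are named. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen.

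The 23 fixed gene lists cover interferon-stimulated genes, JAK-STAT signalling, MHC class I and II, interferon-gamma-type targets, NF-kB, cell death, cell cycle, p53, squamous differentiation, basal identity, mesenchymal genes, cholesterol, unfolded protein response, glycolysis, IRF1-AS partner proteins, interferon-responsive long non-coding RNAs, housekeeping, mitochondrial and histone genes, and markers of leukocytes, stroma and HEK293T cells. Mitochondrially encoded genes are not listed in the IFN-β tables, and 1 of 16 interferon-responsive long non-coding RNAs is listed in the knockdown tables. No MHC class II gene passed the knockdown filter, but of 181 genes with copies on alternate haplotypes 75 are listed at 0 in all 4 libraries (3268 of 22428 others are), among them HLA-DRA, TAP1, PSMB8 and PSMB9, so a 0 there is not read as absent expression. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, while fry asks whether its genes move 1 way on balance. Genes raised by IFN-β (adjusted p under 0.05, 2-fold or more, higher in every line) were tested as a set in the knockdown model, and their median was set against 10000 random lists matched on expression in 20 bins. A further 3 lists (interferon ligands, heat shock chaperones, metallothioneins) were chosen after the values were seen.

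Tests were tried on simulated data first. With a spread smoothed across genes, all simulated changes of 2 log2 units and 74% (IFN-β) and 81% (knockdown) of changes of 1 unit were recovered, but 19 of 193 calls in the IFN-β design and 52 of 233 in the knockdown design were unchanged genes. A second simulation, added after that result, drew each gene's variance from limma's own model, in 5 runs. In the IFN-β design 4.96% of calls were then unchanged genes, and 68.2% of changes of 1 unit and 96.6% of changes of 2 units were recovered. Adding the shift of 0.41 seen in KYSE450 raised the false share to 29.3%. With it limma's median prior degrees of freedom became infinite, as they are for 10828 of 12429 genes in the real fit. The shift also moved the fold change of every gene, and the simulation did not separate these effects. Median-of-ratios scaling brought it to 5.33%. In the knockdown design 12.0% of calls were unchanged genes, and 2% and 47.8% of changes of 1 and 2 units were recovered. The p-values of unscaled IFN-β fits are therefore too small and are not printed for single genes, except where a call was lost, and standard errors of IFN-β fold changes come from the scaled fit.

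Alternatives were other scalings, filters and pseudocounts, no block, a joint fit of all 10 libraries, and each line left out in turn. Those added after the data were seen were limma without its robust option, the parts of the table fitted separately, small structural RNAs left out, transcripts not summed, and haplotype copies not merged. In the knockdown comparison, leaving out a line used the joint fit of 10 libraries, where the remaining pair is assumed to vary like the other libraries and where tables with different totals share a fit.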

Results

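Gene expression was measured by RNA sequencing in human esophageal squamous cell carcinoma (ESCC) cell lines, and 10 libraries in 4 groups were analysed. In the first experiment, KYSE30, KYSE180 and KYSE450 each gave 1 untreated library and 1 library from cells exposed to interferon-beta (IFN-β), an antiviral cytokine of the type I interferons, at 1000 IU/ml for 72 h. In the second, KYSE30 and KYSE180 each gave 1 vector control library and 1 library after lentiviral knockdown of IRF1-AS, a long non-coding RNA antisense to the transcription factor gene IRF1. The cell lines are the replicates, so the p-values refer to differences between lines and not between cultures of 1 line. For 10828 of 12429 genes in the unscaled IFN-β fit, limma used a spread shared across genes in place of the gene's own. Those p-values, and the calls that rest on them, do not measure how well the lines agreed on that gene. The deposited values are FPKM without read counts, so the depth of each library is unknown and no counting interval can be given. Between 10993 and 11887 protein-coding and other named genes reached 1 FPKM in the libraries of the first experiment, and between 11715 and 12348 genes did in the second.

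The first question was how the IRF1 locus behaved under each treatment. IRF1 lies on the minus strand of chromosome 5 at 132481609 to 132490798 (GRCh38), and C5orf56 (ENSG00000197536), an annotated antisense gene, lies on the plus strand at 132410636 to 132488702 and overlaps it over 7094 bases. Another gene on that strand, AC116366.3, spans all 9190 bases of IRF1 and is not analysed here. The references used here name C5orf56 IRF1-AS1 or CARINH, and the IFN-β tables list it by symbol alone, so the transcripts counted there are not known. After IFN-β, IRF1 went from 7.31 to 19.8 FPKM in KYSE30, from 3.35 to 10.5 in KYSE180 and from 1.44 to 6.01 in KYSE450. C5orf56 went from 1.72 to 6.62 FPKM in KYSE30, from 0.97 to 5.47 in KYSE180 and from 0.38 to 3.93 in KYSE450. Both rose, IRF1 by a log2 fold change of 1.30 ± 0.13 and C5orf56 by 1.59 ± 0.14 (SE, n = 3 lines, limma after median-of-ratios scaling, adjusted p = 0.0161 and 0.0103).

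In the knockdown libraries C5orf56 was lower in KYSE30, while in KYSE180 it was near 1 FPKM in both libraries and no difference is shown. It stood at 6.86 FPKM in the KYSE30 vector control and 3.04 after knockdown, 44.4% of control, and at 1.08 and 0.948 FPKM in KYSE180, 88.0% of control. IRF1 stood at 31.1 and 5.88 FPKM in KYSE30 and at 1.83 and 1.20 FPKM in KYSE180. Neither passed the knockdown test, with a log2 fold change of −0.53 ± 0.30 for C5orf56 and −1.29 ± 0.48 for IRF1 (SE, n = 2 lines, limma, adjusted p = 0.831 and 0.815). Whether reads were counted by strand is not given in the sources used here, so reads from IRF1 and its antisense gene cannot be told apart where they overlap. On the values as deposited, the calls under IFN-β were lost without KYSE450, with an adjusted p of 0.0662 for IRF1 and 0.0626 for C5orf56.

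**Figure D1:**
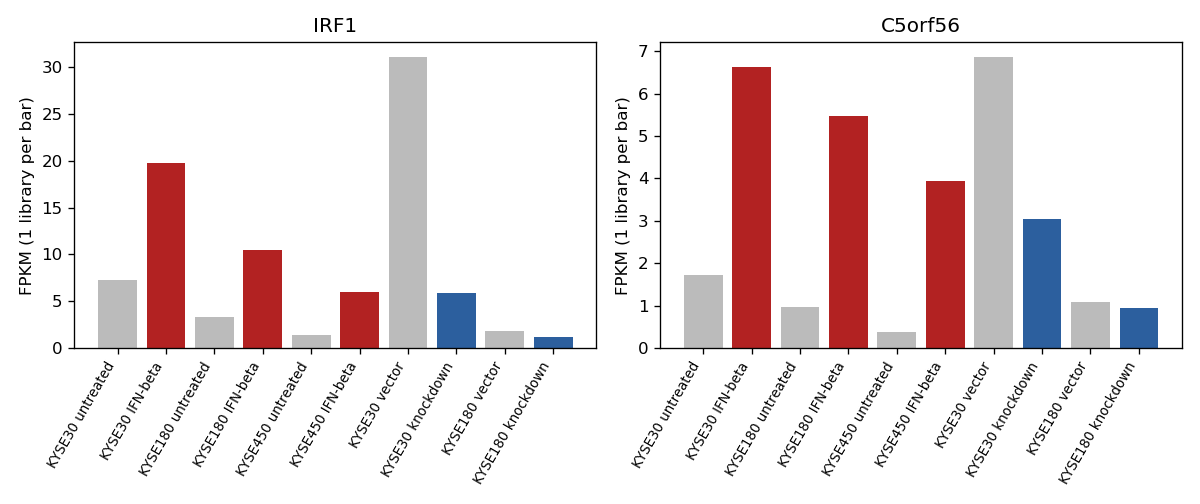
Deposited FPKM of IRF1 (left) and its antisense gene C5orf56 (right), 1 bar per library on linear axes from 0, with no error bars because each bar is 1 library (gray, controls; red, IFN-β; blue, knockdown). Both genes were higher in every IFN-β library than in its control, and the tallest control bars are those of the KYSE30 vector control at 31.1 and 6.86 FPKM.

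The second question was which genes responded to IFN-β in all 3 lines. Among called genes with an average of 5 FPKM or more and 1 direction in every line, the 10 largest rises were all interferon-stimulated antiviral genes. Large rises can be missing from this ranking: OAS1, not among the 10, had log2 ratios of 4.56 in KYSE30, 4.05 in KYSE180 and 7.22 in KYSE450. IFI27 rose from 1.61 to 659 FPKM in KYSE30, from 1.06 to 819 in KYSE180 and from 1.72 to 1075 in KYSE450, a log2 fold change of 8.42, and of 8.27 ± 0.14 after median-of-ratios scaling (SE, n = 3 lines, limma). IFI6 followed at 7.56 (7.42 ± 0.37 scaled, and 8.21, 6.30 and 8.16 in the 3 lines) and OAS2, a sensor of double-stranded RNA, at 7.11 (7.02 ± 0.19 scaled). IFIT3 rose by 6.05, IFI44 by 5.98, TRIM22 by 5.83, the ubiquitin-like modifier ISG15 by 5.75, IFIT1 by 5.57, OAS3 by 4.25 and OASL by 4.07. After median-of-ratios scaling 8 of these 10 were called, IFI27 with an adjusted p of 7.52e-06 and IFIT1, the weakest, with 0.0110, while IFI44 had 0.0502 and OAS3 0.0963.

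Among the type I interferon-stimulated genes, 33 of 48 measured members rose and none fell. The count was 36 when adjusted over the list alone, and 17 after median-of-ratios scaling. Of the 48, 47 were higher in every line, and the list's median log2 ratio was 3.42 in KYSE30, 2.26 in KYSE180 and 4.49 in KYSE450. In the interferon receptor and JAK-STAT list, 5 of 19 rose, and the count adjusted over the list alone was also 5. IRF9, which carries the interferon signal to the nucleus together with STAT2, rose by 2.94 (2.29, 2.24 and 4.30 in KYSE30, KYSE180 and KYSE450) and STAT2 by 1.92 (2.48, 0.80 and 2.48). After scaling they had 2.83 ± 0.36 and 1.78 ± 0.32 (SE, n = 3 lines, limma), with adjusted p of 0.0963 and 0.208, while IRF1 kept its call.

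**Figure D2:**
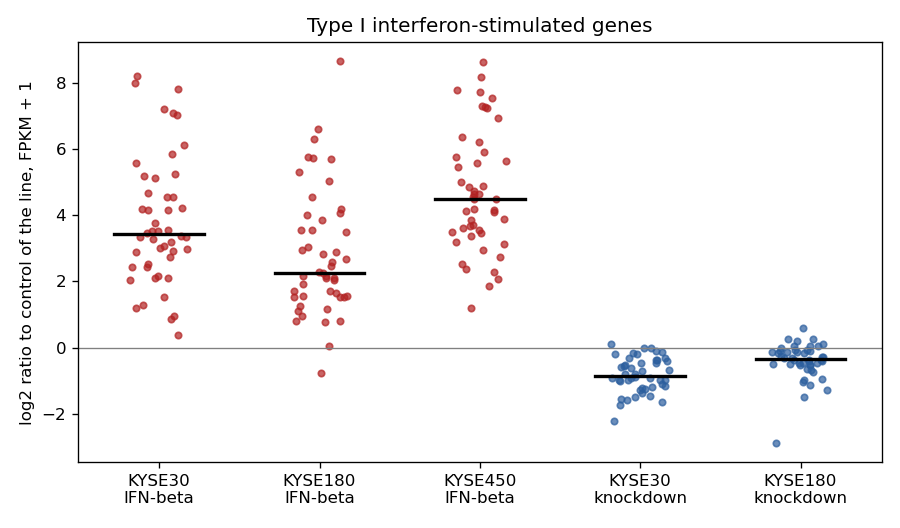
Log2 ratio to the control of the same line (FPKM + 1, vertical axis) for each measured type I interferon-stimulated gene, with 1 point per gene, sideways scatter for legibility only, and a black line at the median (red, IFN-β, 48 genes; blue, knockdown, 46 genes). The medians were 3.42, 2.26 and 4.49 after IFN-β and −0.84 and −0.33 after knockdown.

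All 18 measured genes of MHC class I antigen presentation rose, also when adjusted over the list alone. After median-of-ratios scaling HLA-B rose by a log2 fold change of 3.90 ± 0.15, HLA-C by 2.85 ± 0.16, the shared light chain gene B2M by 2.56 ± 0.14 and the immunoproteasome subunit gene PSMB9 by 3.80 ± 0.36 (SE, n = 3 lines, limma). All 4 were called with that scaling, as were 9 of the 18 genes of the list. HLA genes are near-identical in sequence, and how the authors' counting divided shared reads is not given in the sources used here. Of the interferon-gamma-type and IRF1 targets, 10 of 12 rose, over all genes and over the list alone, among them NMI (2.52), the peptidase gene LAP3 (1.89), GBP1 (2.22) and APOL1 (2.05), with 2 calls after scaling, LAP3 and APOL1. Of the MHC class II list only CTSS, a lysosomal protease gene, passed the filter, and it rose by 1.21 but had an adjusted p of 0.385 after scaling.

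Smaller rises came from inflammatory, stress and cell death genes, and none of these kept its call after median-of-ratios scaling. In the NF-kB inflammatory list 3 of 12 rose (7 adjusted over the list alone), namely the chemokine genes IL8 (log2 fold change 2.04) and CCL5 (1.04) and PTGS2 (0.96). In the unfolded protein and integrated stress response list 5 of 22 rose (13 over the list alone), including the endoplasmic reticulum chaperone gene HSPA5 (1.12), DDIT3 (1.16), ASNS (0.78) and ATF3 (0.94). Of 19 cell death genes, the death ligand gene TNFSF10 (1.10) and PMAIP1 (0.99) rose (6 over the list alone). RRM2 (0.79) rose among 31 cell cycle genes (2 over the list alone) and GDF15 (1.17) among 17 p53 targets (1 over the list alone). Of 14 histone genes, HIST1H1D (1.07), HIST2H2AA3 (0.90) and HIST2H2BE (0.92) rose and HIST1H4C (−0.75) fell, and adjusted over the list alone 5 rose and 3 fell.

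Falls were ranked under the same conditions as the rises, among called genes. The largest were SNHG19 (log2 fold change −3.51), the prostaglandin-degrading enzyme gene HPGD (−1.50) and the decoy death receptor gene TNFRSF10D (−1.28). LINC00472 (−1.10), FAM83H-AS1 (−1.07), the basal keratin gene KRT15 (−0.99) and ACO1 (−0.98) came next. The collagenase gene MMP1 (−0.91), HIST1H3E (−0.90) and H19 (−0.88) came last, and none of the 10 was called after median-of-ratios scaling. Of these, ACO1 (0.0521), SNHG19 (0.0566) and HIST1H3E (0.0566) had the smallest adjusted p in limma after scaling. Several were barely lower in 1 line. In KYSE30 HPGD went from 0.07 to 0.05 FPKM and MMP1 from 0.59 to 0.42, and KRT15 had a log2 ratio of −0.22. TNFRSF10D had −0.18 in KYSE180 and LINC00472 −0.03 in KYSE450. KRT4 (−0.91) fell among 16 keratinocyte differentiation genes (2 adjusted over the list alone), KRT15 and KRT5 (−0.73) among 15 basal squamous genes (3 over the list alone), MMP1 among 15 mesenchymal genes (1 over the list alone), NDRG1 (−1.14) among 21 glycolysis and hypoxia genes (1 over the list alone) and RPLP0 (−0.63) among 14 housekeeping genes (1 over the list alone). KRT4 and NDRG1 were not lower in KYSE30 (0.06 and 0.02), and the median of the keratinocyte list was 0.03 in KYSE30, −0.78 in KYSE180 and −0.04 in KYSE450. Of 24 cholesterol biosynthesis genes, of 3 partner proteins linked to IRF1-AS in the field and of 5 markers of HEK293T packaging cells, none was called, over all genes or over the list alone. The leukocyte marker CD68 rose by 1.04, and no fibroblast or endothelial marker passed the filter. KRT4, KRT5, NDRG1, RPLP0 and CD68 were not called after scaling either, with adjusted p between 0.0749 and 0.494.

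Over all 12429 genes tested with limma, 237 passed an adjusted p of 0.05, 193 higher and 44 lower after IFN-β, and 147 of them changed 2-fold or more (137 higher, 10 lower). The count is too generous. In KYSE450 the median of all genes lay 0.41 log2 units above its control, against −0.01 in KYSE30 and −0.02 in KYSE180. The long non-coding part did not share that shift, with medians of 0 in KYSE450, 0.27 in KYSE180 and −0.06 in KYSE30. Simulated data with a shift of 0.41 in every gene gave 29.3% unchanged genes among the calls, against 4.96% without it and 5.33% after median-of-ratios scaling. With that scaling 50 genes were called, all higher and all among the 237, so the share of higher calls went from 81.4% to 100%. Some other fits gave fewer calls too, but they differ in more than the shift and do not measure the excess. Without KYSE450, and so with fewer lines, the count was 35. Without the line as a block, which leaves differences between lines in the spread, it was 15. With no filter on low values it was 30. In the untreated and treated KYSE450 libraries the structural RNAs RMRP and RPPH1 held 38.4% and 26.5% of the summed values, and they held between 37.2% and 41.9% in the other libraries.

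**Figure D3:**
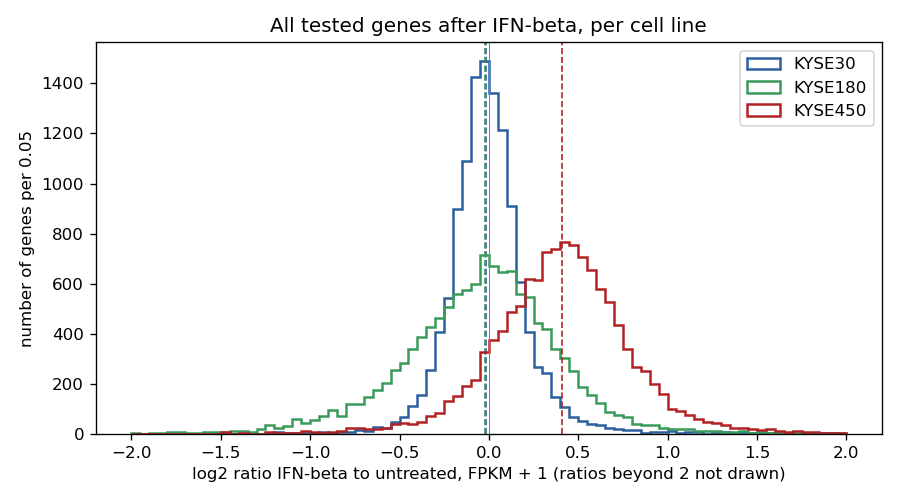
Distribution of the log2 ratio of IFN-β to untreated (FPKM + 1, horizontal axis) over all 12429 tested genes in each line, as the number of genes per bin of 0.05, with dashed lines at the medians of −0.01 (KYSE30), −0.02 (KYSE180) and 0.41 (KYSE450). Ratios beyond 2 are not drawn, and the KYSE450 distribution lies to the right of the others.

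As sets, 10 of 19 testable lists were called by limma's camera test with a preset correlation. The lists of interferon-stimulated genes, MHC class I, interferon-gamma-type targets, JAK-STAT signalling, interferon-responsive long non-coding RNAs, unfolded protein response, NF-kB and cell death were called higher, and keratinocyte differentiation and basal squamous identity lower. None was called with an estimated correlation, where the adjusted p was 0.0640 for interferon-stimulated genes and for MHC class I, 0.109 for interferon-gamma-type targets, 0.321 for the long non-coding RNAs, 0.558 for JAK-STAT, NF-kB and the unfolded protein response, and 0.577 for cell death and the 2 squamous lists. The fry test called none (adjusted p = 0.0731 for MHC class I and 0.105 for interferon-stimulated genes). With 2 residual degrees of freedom and adjustment over 19 lists, these tests did not call even the interferon-stimulated genes, of which 47 of 48 were higher in every line. Their unadjusted p was 0.00545 with an estimated correlation and 0.0165 in fry. Cell cycle genes (adjusted p = 0.0654), p53 targets (0.806), mesenchymal genes (0.203), cholesterol biosynthesis (0.752), glycolysis (0.483), the IRF1-AS partner proteins (0.804), housekeeping genes (0.310), histone genes (0.752) and HEK293T markers (0.752) were not called by camera with the preset correlation. The cell cycle list was called after scaling (0.0256), without the block (0.0137), without KYSE30 (0.00895) and without KYSE450 (0.0223). Both squamous lists lost their call without KYSE180 (0.202 and 0.193), the basal list also without the block (0.0576) and NF-kB at an average of 5 FPKM (0.0674).

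Because the series concerns interferon-regulated long non-coding RNAs, these were counted apart. Of 806 long non-coding RNA genes tested, 26 passed the test, 19 higher and 7 lower, and 36 did when adjusted over these genes alone (25 higher, 11 lower), but fitted apart from the other genes limma called 0 (27 at an unadjusted p under 0.05, smallest adjusted p 0.0619). The strongest rises were RP11-609D21.3 (chromosome 17, 6772831 to 6776116), BISPR (chromosome 19, 17405686 to 17419324), next to the antiviral gene BST2, the small Cajal body RNA gene SCARNA9, CTD-2095E4.5 and RP11-12J10.4, with log2 fold changes of 2.90, 2.76, 2.47, 1.79 and 1.54 (coordinates in GRCh38). The strongest falls were SNHG19, ENSG00000272579.1 (−1.21), LINC00472, FAM83H-AS1 and RP11-392P7.6 (−1.01). Among them, ENSG00000272579.1 was not lower in KYSE450 (log2 ratio 0.08), and RP11-392P7.6 had −0.03 in KYSE180. After median-of-ratios scaling 1 of the 806 was called, RP11-609D21.3 (2.83 ± 0.20, SE, n = 3, limma, adjusted p = 0.00380), and without KYSE450 the count was 4. Long non-coding RNAs tested in the named-gene part are not among the 806. C5orf56 is such a gene, and it was called after scaling (1.59 ± 0.14, limma, adjusted p = 0.0103). The scaling used the same factor for both parts of a library, though their medians differed. Scaled values of the 806, also among the falls above, may therefore be shifted. In the fixed list of interferon-responsive long non-coding RNAs, 3 of 6 tested members were higher in every line. BISPR alone was called, over all genes and over the list alone. NEAT1 (0.50), HCG4 (0.48) and HCP5 (2.39), which were taken from the named-gene part, were not. NEAT1 is in both parts, with log2 ratios of 0.30, −0.02 and 1.21 in KYSE30, KYSE180 and KYSE450 there. In the long non-coding part it had 0.76, 0.76 and 0.18. The difference between BISPR and HCP5 depends on the fit: HCP5 was called without limma's robust option. After scaling limma called neither BISPR nor HCP5 (adjusted p = 0.129 and 0.494).

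Within each line, genes were also counted by size alone, with no test because each line has 1 library per arm. KYSE30 had 208 genes higher and 62 lower by 2-fold or more after IFN-β, KYSE180 had 294 and 392, and KYSE450 had 773 and 80. After median-of-ratios scaling the KYSE450 counts were 270 and 201. The 3 lines shared 85 genes that were 2-fold higher, against 0.175 for independent lists, and 1 that was 2-fold lower, against 0.00437. IFI27 and IFI6 were among the 3 largest rises of each line, with OAS2 beside them in KYSE180 and BST2, a gene that tethers virus particles, in KYSE450. In KYSE30 the largest ratio was that of RP5-940J5.9, listed at 0 in the control and at 646 FPKM after IFN-β. The largest falls were RN7SL1 (5213 to 41.6 FPKM), SNHG19 and SNHG10 in KYSE30, RPPH1 (18571 to 0.701 FPKM in the long non-coding part of the table, 118833 to 120903 in its other part), RP4-816N1.6 and AC009133.12 in KYSE180, and SNORD27, U47924.29 and RP11-159D12.6 in KYSE450.

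The third question was which genes differed after knockdown of IRF1-AS. None passed the test, and the genes named here are those with the smallest unadjusted p in each direction. Higher by value in both lines were HSPA1A, a heat shock chaperone gene, at 17.4 and 79.5 FPKM in KYSE30 (control, then knockdown) and at 6.29 and 45.0 in KYSE180, and the small GTPase gene RAP1B, at 14 and 49.6 in KYSE30 and at 12 and 46.2 in KYSE180. F11R, a junctional adhesion gene, TRMT6 and the activin antagonist gene FST had log2 fold changes of 1.53 ± 0.18, 1.35 ± 0.20 and 1.24 ± 0.19 (SE, n = 2 lines). Lower by value were DNAJC25-GNG10 (−3.80), the protease inhibitor gene SLPI (−2.41 ± 0.26), SEPTIN5 (−1.67), the calprotectin subunit gene S100A9 (−2.03) and PDLIM1 (−1.40). SLPI stood at 34.4 and 7.76 FPKM in KYSE30 and at 874 and 124 in KYSE180. HSPA1A shares reads with its near-identical copy HSPA1B, which stood at 28.6 and 41.8 FPKM in KYSE30 and 47.4 and 66.8 in KYSE180, and DNAJC25-GNG10 is a readthrough gene that overlaps DNAJC25 and GNG10.

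No gene passed the knockdown test. Of 12813 genes tested with limma, 0 had an adjusted p under 0.05, the smallest was 0.259 (DNAJC25-GNG10), and 770 had an unadjusted p under 0.05, 251 higher and 519 lower. Limma without its robust option also called 0 genes (800 unadjusted), and a joint fit of all 10 libraries called 73, 17 higher and 56 lower. With 2 lines and 1 residual degree of freedom the test recovered 47.8% of simulated changes of 2 log2 units and 2% of changes of 1 unit with variances from limma's model, and 100% and 81% with a smoothed spread, where 52 of 233 calls were unchanged genes. A count of 0 does not show that the genes were unchanged. Across genes, which are not independent replicates, the log2 ratios of the 2 lines had a Pearson correlation of 0.09.

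Several fixed gene lists leaned lower after knockdown. Of 46 measured type I interferon-stimulated genes, 37 were lower in both lines and none was higher in both, with a median log2 ratio of −0.84 in KYSE30 and −0.33 in KYSE180. The KYSE30 vector control stood apart, with these genes at a median rank percentile of 72.1 against 50 in untreated KYSE30 of the other experiment, and the interferon gene IFNL1 at 88.9 FPKM (20.6 after knockdown). IFIT1 stood at 116 and 58.5 FPKM in KYSE30 and at 14.9 and 4.70 in KYSE180, and OAS1, OAS2 and OAS3 had log2 fold changes of −0.96, −0.96 and −0.82. TAP1, PSMB8 and PSMB9 are listed at 0 in all 4 knockdown libraries, as are 75 of 181 genes with copies on alternate haplotypes, and were not tested. Of the 15 other MHC class I genes 11 were lower in both lines, including HLA-B (−0.85), B2M (−0.82) and HLA-E (−0.89). Of 24 cholesterol biosynthesis genes 19 were lower in both lines, among them INSIG1 (−1.36), FDFT1 (−1.01) and HMGCS1 (−1.02). Of 23 keratinocyte differentiation genes 11 were lower in both lines, and their median log2 ratio was −0.03 in KYSE30 and −0.78 in KYSE180. No member of any list was called over all genes. Adjusted over the list alone, 7 cholesterol genes, 6 keratinocyte differentiation genes (among them S100A9, KRT16, SPRR3 and SPRR1A), 3 interferon-gamma-type targets (CASP1, GBP2 and SECTM1) and 3 NF-kB genes (TNFAIP2, NFKBIA and NFKB2) were lower, KRT14 was lower and KRT15 higher in the basal squamous list, and the other lists had 0.

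As sets, camera with the preset correlation called 10 of 19 lists. Lower were interferon-stimulated genes (median log2 fold change −0.59), MHC class I (−0.46), interferon-gamma-type targets (−0.49), NF-kB (−0.88), keratinocyte differentiation (−0.60), cholesterol biosynthesis (−0.69), the unfolded protein response (−0.38, led by DDIT4), glycolysis (−0.14, led by BNIP3) and p53 targets (−0.13, led by PHLDA3), and cell cycle genes (0.18, led by MCM5) were higher. None was called with an estimated correlation (adjusted p = 0.651 for glycolysis and 0.631 for each of the other 9). Fry called none either (adjusted p = 0.772 for glycolysis, 0.775 for cell cycle genes and 0.486 for the rest). Both tests rest on 1 residual degree of freedom, and MHC class I lost its call although its estimated correlation was −0.03. These losses therefore do not show that the lists were unchanged. Without KYSE30 the NF-kB (0.0539), p53 (0.424) and unfolded protein (0.220) lists lost their call and the cell cycle list changed direction (0.274), and without KYSE180 the p53 list lost its call (0.0825) and the glycolysis list changed direction (0.635). JAK-STAT signalling (adjusted p = 0.0678), cell death (0.319), basal squamous (0.319), mesenchymal (0.263), IRF1-AS partner (0.0678), housekeeping (0.904), mitochondrially encoded (0.594), histone (0.308) and HEK293T marker (0.667) genes were not called. JAK-STAT signalling was called at an average of 5 FPKM (0.0124), and the IRF1-AS partner list without the block (0.0301) and without KYSE180 (0.0340). Leukocyte markers (CD68 and CSF1R) and the 1 measured fibroblast or endothelial marker (ENG) were too few to test and not called.

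The fourth question was whether genes that IFN-β raised were affected by the knockdown. Of the 136 genes that were called, raised 2-fold or more in the fit and higher in all 3 lines, 112 were measured in the knockdown experiment, which shares no library with the first, and 79 of these were lower in both lines and 2 higher in both. Over all tested genes 25.4% were lower in both lines and 26.7% higher. The median log2 ratio of the 112 genes was −0.51 in KYSE30 and −0.31 in KYSE180. In each line it was below all 10000 random lists matched on expression, whose middle 95% was −0.06 to 0.11 in KYSE30 and −0.08 to 0.06 in KYSE180. Camera with the preset correlation called the set lower (p = 5.88e-19), but an estimated correlation gave p = 0.163 and fry p = 0.116. The last 2 tests rest on 1 residual degree of freedom here. Neither called any fixed list after adjustment over the lists. Before adjustment, the interferon-stimulated genes under IFN-β had p = 0.00545 with an estimated correlation and 0.0165 in fry, with 2 residual degrees of freedom. With 1, and with every fixed list uncalled under knockdown, the tests cannot decide whether the shift is more than genes moving together. The 46 measured genes raised 4-fold or more had a median of −0.53 (p = 1.91e-17 in camera, 0.126 with an estimated correlation), and the 23 measured genes that fell after IFN-β had a median of −0.05 (p = 0.810 in camera). The members were chosen on values as deposited, which overstate the number of IFN-β genes.

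Within the lines, knockdown went with 200 genes higher and 444 lower by 2-fold or more in KYSE30, and with 190 higher and 345 lower in KYSE180, again without a test. Both lines shared 41 genes that were 2-fold lower, against 7.65 for independent lists, and 14 that were 2-fold higher, against 2.40. The largest ratios were those of HSPE1-MOB4 (0.111 and 196 FPKM), AC006486.9 and FIS1 (8.89 and 72.1 FPKM) in KYSE30 and of an unnamed transcript, CTD-2410N18.5 and TUBB in KYSE180. The lowest were TUBB, an unnamed transcript and DNAJC25-GNG10 in KYSE30, and RP11-1035H13.3, C6orf15 and SRA1 in KYSE180. HSPE1-MOB4 is a readthrough gene that overlaps HSPE1 and MOB4, where shared reads can be divided differently between libraries.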

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

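The test of unstable long non-coding estimates below was chosen after its values were seen, and the differences between lines given first were found by their size alone and were not tested.

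Among the genes named within a line, 7 moved in opposite directions in 2 lines. After IFN-β the log2 ratio of SNHG10 was 1.29 in KYSE180 and −3.42 in KYSE30, that of RP4-816N1.6 was 3.08 in KYSE30 and −4.90 in KYSE180, and that of RP11-159D12.6 was 1.16 in KYSE180 and −4.30 in KYSE450. After knockdown AC006486.9 stood at 3.50 in KYSE30 and −1.96 in KYSE180, TUBB at 3.87 in KYSE180 and −4.47 in KYSE30, RP11-1035H13.3 at 3.14 in KYSE30 and −4.30 in KYSE180, and SRA1 at 1.18 in KYSE30 and −3.76 in KYSE180. TUBB stood at 22.5 and 0.06 FPKM in KYSE30 (control, then knockdown) and at 0.018 and 13.9 in KYSE180. Its ratio therefore rests on 1 value near 0 in each line, and how its reads were assigned is not given in the sources used here. Each line has 1 library per arm, so none of these differences has a replicate check.

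The large falls of long non-coding RNAs after IFN-β can be checked where a gene is listed in both parts of a table. Of 10 falls of 2-fold or more in the long non-coding part, at an average of 5 FPKM or more in both parts, 1 was also 2-fold in the other part, SNHG10 in KYSE450 (−1.31 and −1.25). In KYSE30 0 of 5 falls were 2-fold in the other part (SNHG10 had −3.42 and −0.04, SNHG3 −2.16 and 0.02). Unstable estimates in the long non-coding part would give this, but so could picking falls by their size in that part. Over 25 genes compared without that choice, 7 differed between the parts by 1 log2 unit or more in KYSE30, 3 in KYSE180 and 2 in KYSE450. The ratios of the parts correlated across these genes at 0.10, 0.23 and 0.72. In KYSE180 (0 of 2) and KYSE450 (1 of 3) the falls are too few to decide, and not all differed between the parts: RPPH1 in KYSE180 had −13.41 and 0.02, while MALAT1 there had −1.10 and −0.92, and in KYSE450 H19 had −1.15 and −0.998 and SCARNA2 −1.04 and −0.70 (H19 in KYSE180, below the minimum, had −1.11 and −0.95). SNHG19, the largest called fall, is in the long non-coding part alone and has no such check, and no biological explanation was tested.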

How the results depend on the processing

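The fits without limma's robust option, with the parts of the table apart, without small structural RNAs, with transcripts not summed and with haplotype copies not merged were tests chosen after the data were seen. Count-based tests (DESeq2), TMM or RLE scaling of counts and prior counts of 0.5 and 5 were not run, because the files hold no counts. Depth is unknown, so it set no limit that could be computed. Over the single genes and lists, 1932 comparisons with an alternative kept direction and side of the threshold, 340 lost a call, 63 gained one and 27 changed direction. Of the comparisons for the main answers, 77 were the same, 35 moved by over 1.5 times, 8 lost a call and 1 gained one. Except where a reason is given, the cause was not tested.

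The count of 237 genes changed by IFN-β was 50 with median-of-ratios scaling (all 50 among the 237), 87 without small structural RNAs (85 shared), 128 in a joint fit of all 10 libraries, 147 with a 2-fold change required, and 30 with no filter on low values (30 shared). Without the replicate block it was 15 (15 shared). Leaving out a line gave 35 (without KYSE450, 31 shared) to 183 (without KYSE180, 141 shared). The prior degrees of freedom, infinite for most genes in the fit as reported, were finite with scaling (4.37), without KYSE450 (5.00), with no filter (4.29), without the block (3.50) and without small RNAs (5.97). The 26 long non-coding RNAs became 1 with scaling, 2 with no filter, 2 without the block, 12 at an average of 5 FPKM, 17 with a 2-fold change required, 5 without small RNAs, 41 without the robust option, 47 with transcripts not summed, and 4 to 25 with a line left out. With the parts fitted apart limma called 0 long non-coding RNAs (27 at an unadjusted p under 0.05).

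The knockdown count was 0 in limma with other scalings, filters, pseudocount, no block and no robust option, with 70 to 921 genes at an unadjusted p under 0.05. It was 73 in the joint fit, and 231 (without KYSE30) and 307 (without KYSE180) with a line left out of that fit. There the spread comes from all libraries, and the lone pair left has no spread of its own.

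At the IRF1 locus, the call of IRF1 under IFN-β (log2 fold change 1.42) was lost with no filter (1.42, adjusted p = 0.126) and without the block (1.42, adjusted p = 1.0), and its value was 1.36 to 1.46 with a line left out (adjusted p = 0.0662 without KYSE450). That of C5orf56 (1.68) was lost with no filter (1.68, adjusted p = 0.0592) and without the block (1.68, adjusted p = 0.723), and was 1.6 to 1.78 with a line left out (adjusted p = 0.0626 without KYSE450). Under knockdown IRF1 was −2.22 without KYSE180 (adjusted p = 0.000101) and −0.36 without KYSE30.

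The 10 lists called under IFN-β and the 10 under knockdown each became 0 with an estimated correlation and 0 with fry. With a line left out they were 8 to 11 and 6 to 9. The IFN-β-induced set had p = 0.163 with an estimated correlation and 0.116 with fry in the knockdown model.

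Counts of 2-fold genes within a line moved at an average of 5 FPKM to 160 (KYSE30 IFN-β, from 270), 447 (KYSE180 IFN-β, from 686), 367 (KYSE30 knockdown, from 644) and 311 (KYSE180 knockdown, from 535). A pseudocount of 0.1 gave 1086 (KYSE180 IFN-β), 1472 (KYSE450 IFN-β, from 853), 1057 (KYSE30 knockdown) and 908 (KYSE180 knockdown). Scaling gave 471 in KYSE450.

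Alternatives were followed for the named genes, and none of these that was called changed direction. Among those not called, scaling turned DHX9 (−0.10) and ILF2 (−0.025) under IFN-β. With a line left out, IFN-β values ranged from −0.12 to 0.15 for DHX9 and −0.35 to 0.23 for ZNF711. Knockdown values ranged from −0.033 to 0.34 for ILF2, −0.049 to 0.26 for LIN28B and −0.047 to 0.22 for ZNF711.

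Lists that changed direction under IFN-β had these adjusted p: with fry, cholesterol biosynthesis 0.758, glycolysis 0.757 and housekeeping 0.938. With scaling, histone genes had 0.924. At an average of 5 FPKM p53 targets had 0.849. Without the block p53 targets had 0.848 and histone genes 0.357. With a line left out the range was 0.166 to 0.710 for cholesterol biosynthesis, 0.258 to 0.826 for glycolysis, 0.455 to 0.935 for p53 targets, 0.437 to 0.618 for histone genes and 0.610 to 0.998 for IRF1-AS partner proteins. Under knockdown it was 6.80e-07 to 0.274 for cell cycle genes, 2.24e-08 to 0.635 for glycolysis, 0.512 to 0.805 for basal squamous genes, 0.832 to 0.879 for housekeeping, 0.172 to 0.709 for histone genes and 0.805 to 0.879 for HEK293T markers. Of the lists called under knockdown, cell cycle genes turned direction without KYSE30 and glycolysis without KYSE180.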

Other observations

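The tests of the 2 patterns weighed here, and the 3 gene lists described first, were chosen after the values were seen, while those on other splits of the libraries were chosen before.

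Interferon transcripts and the chemokines that accompany them were present in the KYSE30 vector control and lower in its knockdown library. IFNB1 stood at 6.68 and 1.26 FPKM (control, then knockdown), IFNL1 at 88.9 and 20.6, IFNL2 at 77.1 and 16.5, IFNL3 at 76.9 and 18.8, CCL5 at 158 and 42.2, CXCL10 at 19.7 and 4.82 and CXCL11 at 3.65 and 0.838. All 7 were under 0.2 FPKM in both KYSE180 libraries. Untreated KYSE30 of the other experiment lists IFNB1 and the 3 IFNL genes at 0. Type I interferon-stimulated genes had a median rank percentile among genes listed in both experiments of 50 in untreated KYSE30, 72.1 in its vector control, 59.4 after knockdown and 92.7 after IFN-β. In KYSE180 it was 52.0, 57.5, 53.4 and 88.1. Of 52 genes, 42 ranked higher in the vector control than in untreated cells of KYSE30 and 37 in KYSE180, and the experiments differ in more than the vector.

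Heat shock chaperones and metallothioneins, which bind zinc and copper, are given as values for each line. Of 14 chaperone genes 11 were higher after knockdown in KYSE30 (median log2 ratio 0.59, HSPA8 at 179 and 539 FPKM) and 8 in KYSE180 (0.03), and after IFN-β 6 were higher in KYSE30 (−0.03), 9 in KYSE180 (0.14) and 13 in KYSE450 (0.70, where the median of all genes was 0.41). Of 8 metallothionein genes 3 were higher and 1 lower after IFN-β in KYSE30, 2 and 2 in KYSE180 and 4 and 0 in KYSE450, with the other 4 (MT1A, MT1G, MT1H and MT1M) at 0 in all 6 libraries, and after knockdown 0 and 5 in KYSE30 and 1 and 4 in KYSE180. MT2A stood at 371 and 557 FPKM in KYSE30 (untreated, then IFN-β), 142 and 276 in KYSE180 and 132 and 828 in KYSE450, and after knockdown it was at 43.7 against 45.2 in KYSE30 and 21.3 against 64.0 in KYSE180. MT1X stood at 9.93 and 2.08 FPKM in KYSE30 (control, then knockdown) and at 51.5 and 4.07 in KYSE180, and with IFN-β it went from 82.4 to 84.6 in KYSE30, 208 to 121 in KYSE180 and 73.2 to 178 in KYSE450. No list and no difference between lines was tested here.

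Of 112 genes induced by IFN-β, 79 were lower in both knockdown libraries, but no single gene passed. The set of these genes did not pass camera with an estimated correlation (p = 0.163) or fry (p = 0.116). Both rest on 1 residual degree of freedom and cannot decide the question. A general shift of genes at their expression level is argued against, since the median of −0.31 in KYSE180, like that in KYSE30, lay below all 10000 matched random lists. A candidate explanation for KYSE30 is interferon made by the vector control cells, whose IFNB1 and IFNL transcripts summed to 250 FPKM. In KYSE180 they summed to 0.199 FPKM, under the 1 FPKM asked for in KYSE30, which goes against interferon made there, but the test in KYSE180 was set so that a low level could not exclude it. With 1 library per arm, less interferon in the KYSE30 knockdown culture and a direct effect of IRF1-AS cannot be told apart, and an effect in KYSE180, where C5orf56 stood at 88.0% of control near 1 FPKM, stays open and untested.

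The median gene was higher after IFN-β in KYSE450. Without small structural RNAs, which took a smaller share of the treated library, the median log2 ratio of its named genes went from 0.43 to 0.21, and those of KYSE30 and KYSE180 were 0.04 and 0.05. About as much of the shift remained as was removed, so these RNAs may account for part of it. The test's bound was 0.21 as well, and that a value this near it decides nothing was settled after it was seen. A true rise of many genes under IFN-β in this line stays open, since totals that are rescaled to a common sum cannot show it.

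The 6 IFN-β libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 237 genes, 26 long non-coding RNAs and 10 lists, and the highest of the other splits gave 37, 24 and 9. After median-of-ratios scaling the real split gave 50 genes and the highest other 1. As the lines pair the libraries, the 3 other splits that part all 3 pairs gave 0, 29 and 37 genes, and the 6 that part 1 pair gave 0 to 26.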
